A study of Mus musculus with 4 samples.

How the data were processed

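The series holds 4 two-colour oligonucleotide arrays of mouse embryonic fibroblasts (MEFs). Each compares cells transfected with the homeobox transcription factor Dlx3, per the labels, with a control on the same slide. Per the labels, 2 arrays hold cells stably transfected with a Dlx3 plasmid in the Cy5 channel and cells transfected with an empty plasmid in the Cy3 channel. The other 2 hold cells transfected for 24 h in the Cy5 channel and control MEFs in the Cy3 channel. The titles call the second array of each group a biological repeat, so the arrays of a group were treated as separate samples, with 2 arrays per group. Total RNA was extracted on RNeasy columns and labelled through aminoallyl nucleotides, per the labels' protocols. All arrays carry the dyes in the same orientation, so a dye effect specific to a probe stays in every ratio, and it cancels in the difference between the groups only where it is of equal size in both.

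Each deposited scanner table gives, per the file headers, the foreground and local background intensity of 17664 spots in 32 blocks at 635 nm (Cy5) and 532 nm (Cy3), as read by GenePix Pro 5.0.0.49. The deposited tables also give the percent of saturated pixels per spot, per the file headers. Detector gains were 650 and 590 (635 and 532 nm) on the first stable array, 610 and 590 on the second, 680 and 570 on the first transient array and 670 and 590 on the second. These values are not normalized. The authors' processed values, a signed score per spot in the deposited value table, carry no stated normalization. Set against the scanner values, they behaved as minus the linear ratio of the control over the Dlx3 channel, with column medians of -1.001, -1.007, -1.002 and -1.002. After conversion to log2 of Dlx3 over control, their correlation with the scanner ratio across spots was 0.972, 0.974, 0.893 and 0.91. How the authors centred and scaled them, and the reason for missing values at 11, 9.9, 21.2 and 16.3% of spots, stay unknown. They were used only as an alternative.

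Log2 ratios of Dlx3 over control were computed with limma 3.58.1 in R 4.3.3. Background was corrected with normexp and an offset of 50 on the mean foreground and median background intensity of all spots. Each array was normalized by global loess with control spots at weight 0, and no step was applied between arrays. The 1009 control spots (817 blanks and 192 randomized oligonucleotides) and spots marked bad by the scanner software were left out. Spots marked as not found and saturated spots were kept. Repeated spots of a probe were averaged. A probe was tested when its median foreground exceeded the median background by 2 background SDs, in either channel, on at least 2 of the 4 arrays. This left 14611 probes for contrasts that involve the stable group and 14613 for the transient group.

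The files name probes by sequence accession and by a description. Of 16463 transcript probes, 6678 of 6951 with a RefSeq accession were named through a RefSeq gene table (assembly GRCm38.p6, used for names only), and 5726 were named through a RIKEN or expressed-sequence clone name in the description. Where both routes applied, they gave the same symbol for 845 of 849 probes. The remaining 4059 probes are called by their descriptions, and 11077 tested probes carried a symbol. No probe sequence was read, so no genome position is given.

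A linear model with 1 mean per transfection type was fitted to all 4 arrays with lmFit and eBayes, so that both groups share an estimate of spread with 2 residual degrees of freedom per probe and 4.2 prior degrees of freedom. Contrasts were the stable mean, the transient mean, stable minus transient, and the mean of the 2 groups. P-values are two-sided, and a call is a Benjamini-Hochberg adjusted p under 0.05. A second count, with no test, took probes past 2-fold with the same sign on both arrays of a group. With so few arrays, their number limits the precision of every ratio. Leaving out an array of a group leaves the value of the group's other array, which is then assumed to vary like the other group. Where a channel was not above background on either array of a group, the change is given as at least N-fold. The bright channel's mean was set against the dim channel's, taken per array as the higher of the probe's own signal and the lowest signal above background. These levels come from loess and Aquantile normalized channels and are open to dye bias. The lowest signal above background need not exceed an undetected signal, so the bound is nominal. Where the probe's own dim signal was the higher on both arrays, as for Serf1, the ratio to that undetected signal is given instead, which is not a bound.

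The contrasts, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The rule named Dlx3, Lifr and Chrdl1. It also named, per contrast, the 12 probes with a symbol that rose most and the 12 that fell most among called probes with the same sign on every array concerned. For the difference, both arrays of a group had to lie above both of the other group. From each list it took up to 4 called members with the largest change, or, where none was called, the 2 with the smallest p. Some of the genes this rule names are not reported here. The 24 lists were the DLX and MSX homeobox genes, the HOX cluster, LIF and IL6-family signalling, BMP signalling and antagonists, the WNT pathway, bone and cartilage, epidermis, trophoblast and placenta, pluripotency, interferon response, inflammatory cytokines, cell cycle, p53 targets and growth arrest, extracellular matrix and TGF-beta targets, smooth and skeletal muscle, adipocyte, endothelium, macrophage and blood, neural, heat shock and unfolded protein response, cholesterol synthesis, immediate early genes, oxidative phosphorylation and ribosomal proteins. The muscle, adipocyte, endothelium, macrophage and blood, neural and epidermis lists stand for other cell types a MEF culture could hold. Lists were tested over 10335 genes, each represented by its brightest probe, with limma's camera at a preset correlation of 0.01, with camera at a correlation estimated per list, and with fry. The version with an estimated correlation rests on the 2 residual degrees of freedom, so it had little power to call a list at any correlation. For the neural list in stable minus transient, the estimated correlation was 0. Its unadjusted camera p still went from 0.00031 at the preset correlation to 0.0628. A call lost in that version therefore cannot be put down to the correlation. List p-values were adjusted over the 24 lists. Adjusted p-values of list members come from this gene-level fit.

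The pipeline was tested on simulated data of 14613 probes with known changes. In the simulated stable comparison it recovered 80.6% of probes changed by 0.5 on the log2 scale, 100% of those changed by 1 and 100% of those changed by 2. In the simulated difference it recovered 19.4, 97 and 100%, respectively. Of the calls, 15 of 202 in the stable and 8 of 152 in the difference comparison were unchanged probes. None of 23 unshifted lists was called by camera in that simulation. Simulated genes varied independently, whereas the correlation within lists was estimated at 0.426 for ribosomal proteins and 0.317 for the interferon response. The simulation therefore cannot show how often camera at the preset correlation calls unshifted lists in these data. It also gave both groups the same spread per probe.

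Alternatives covered background correction, normalization within and between arrays, the foreground measure, the filters on dim and marked spots, the model of the spread, the list tests, the authors' processed values and leaving out each array in turn. A filter against the 95th percentile of the randomized oligonucleotides was added after the data were seen. Every array was its own slide and all were scanned on the same day, so no batch term was fitted.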

Results

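Gene expression in Dlx3-transfected MEFs was measured on 4 arrays, 2 of stable transfectants against empty-plasmid cells and 2 of cells transfected for 24 h against control MEFs. The series title sets the question, which is the regulation of Lifr and Chrdl1 by Dlx3 in the differentiation of mouse embryonic stem cells, although the cells on these arrays are fibroblasts. In the stable group, 86.9 and 87.2% of transcript spots lay above local background, against 77.3 and 80.9% in the transient group. Median foreground intensities in the Dlx3 channel were 774 and 813 on the stable arrays and 484 and 574 on the transient arrays. The control channel read 791 and 865 on the stable arrays and 456 and 568 on the transient arrays. The SD of log2 ratios over spots was wider on the stable arrays (0.307 and 0.363) than on the transient arrays (0.227 and 0.219). For the stable group means it was 0.303 over tested transcript spots, 0.218 over blanks and 0.223 over randomized oligonucleotides. For the transient group means it was 0.204, 0.26 and 0.211, respectively. Transient ratios thus spread no wider at transcript spots than at spots without a target. Across probes, log2 ratios correlated with r = 0.637 between the stable arrays and 0.636 between the transient arrays, although probes are not independent replicates.

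The probe for Dlx3 itself, the transfected gene, was not called in either group. It read 0.06 and 0.23 (log2 Dlx3 over control) on the stable arrays, a mean of 0.14 ± 0.12 (SD, n = 2, limma adjusted p = 0.396), and 0.14 and 0.56 on the transient arrays, a mean of 0.35 ± 0.30 (adjusted p = 0.179). Its spot was above background in both channels on all 4 arrays, with intensities of 446 to 1815 in the Dlx3 channel and 382 to 1620 in the control channel, and with 0% of pixels saturated, but it exceeded the 95th percentile of the randomized oligonucleotides in the Dlx3 channel on 0 of 4 arrays. Lifr, the receptor subunit for leukaemia inhibitory factor, rose in stable transfectants by 0.56 ± 0.26 (1.47-fold, n = 2, adjusted p = 0.0194), with its control channel above background on 1 of the 2 arrays. In transient transfectants Lifr read 0.79 ± 0.07 (1.73-fold, adjusted p = 0.065), and over all 4 arrays it rose by 0.68 (adjusted p = 0.00634), with each array positive. Without the second stable array, the stable value of Lifr was 0.38 (adjusted p = 0.0515). Scaling between arrays brought the transient value to 0.95 (adjusted p = 0.00712), and the fit on the transient arrays alone kept 0.79 with an adjusted p of 0.0182.

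Chrdl1, a secreted antagonist of bone morphogenetic proteins (BMPs) listed in the files as neuralin 1, differed sharply between the stable arrays, at -0.06 and 1.45, so that its stable mean of 0.69 ± 1.07 (n = 2) was not called (adjusted p = 0.151). Both transient arrays were high, at 1.20 and 1.14, a mean of 1.17 ± 0.04 (2.25-fold, adjusted p = 0.129 with the spread shared between the groups). Fitted on the transient arrays alone, the same value had an adjusted p of 0.00805. Over all 4 arrays Chrdl1 rose by 0.93 (adjusted p = 0.0324), with 3 of 4 arrays positive. Leaving out either transient array ended this call (adjusted p = 0.119 and 0.111), as did print-tip loess and robust eBayes. A second probe, described as ventroptin-alpha, another name of the same protein, was dimmer and read -0.11 and 0.84 on the stable arrays and 0.28 and 0.40 on the transient arrays (adjusted p = 0.226 and 0.409). None of the 3 title genes was called in stable minus transient, with -0.21 for Dlx3, -0.23 for Lifr and -0.48 for Chrdl1 (adjusted p = 0.505, 0.416 and 0.568). The difference for Chrdl1 was -1.23 without the second stable array (adjusted p = 0.0149) and 0.28 without the first, and that for Dlx3 was 0.002 without the second transient array. Dlx3, Lifr and Chrdl1 did not pass the filter against randomized oligonucleotides, so their values, the Lifr call included, come from spots no brighter than the brightest spots without a target. These genes were chosen by the study, so their direction is not independent evidence.

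**Figure D1:**
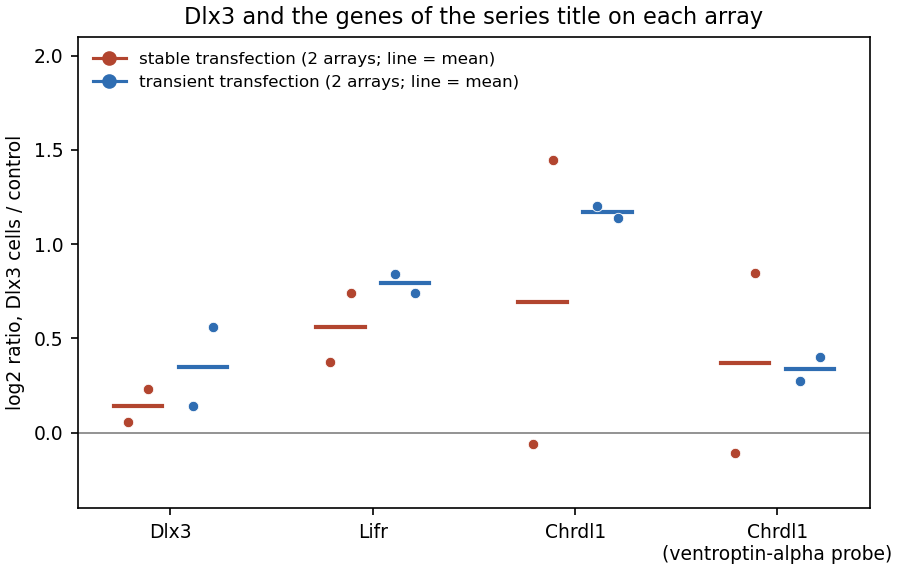
Log2 ratio of Dlx3 cells over control for the title genes, with a point for each array, a line at each group mean of 2 arrays, and stable and transient transfection in separate colours. Lifr lies between 0.38 and 0.84 on all 4 arrays, whereas Chrdl1 reads -0.06 on 1 stable array and 1.14 to 1.45 on the other arrays.

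Stable transfectants differed from empty-plasmid cells at 3320 of 14611 probes, 1693 higher and 1627 lower, with a median size of 0.43 on the log2 scale. The stable arrays fitted alone, or without either transient array, gave 1228 calls, close to the 1288 of the transient arrays alone, and leaving out the second stable array gave 2063. The largest rises were of Tcim, a regulator of transcription, by 3.18 ± 0.52 (SD, n = 2, 9.07-fold), Spp1, the bone matrix protein osteopontin, by 3.17 ± 0.35 (8.97-fold), Msln, the surface protein mesothelin, by 2.78 ± 0.53 and Cdkn1c, an inhibitor of cyclin-dependent kinases, by 2.46 ± 0.66 (adjusted p = 0.00239, 0.00234, 0.00246 and 0.00453). Enpp2 (autotaxin, which makes lysophosphatidic acid) rose by 1.77 ± 0.10, Cthrc1, a collagen-related protein, by 1.57 ± 0.14 and the matrix metalloproteinase Mmp2 by 1.40 ± 1.13, at 0.60 and 2.20 on the arrays. The cytokine Il33 (1.92, at 2.96 and 0.88, control channel above background on 1 of 2 arrays) and the chemokine Cxcl5 (1.85, at 1.06 and 2.64) also rose, as did Fuca2 (1.67), Rin2 (1.49) and Gas1 (1.44).

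The largest falls in stable transfectants were of Ndrg4 (-2.15 ± 0.17, 4.44-fold), the RNA-binding protein Khdrbs3 (-2.05 ± 0.33, 4.14-fold) and smooth muscle actin Acta2 (-1.62 ± 0.72, 3.07-fold), with adjusted p = 0.00234, 0.00246 and 0.0104. The actin-binding protein Tagln fell too (-1.16 ± 0.03), as did the WNT ligand Wnt10b (-1.36 ± 0.32), Tmeff2 (-1.31), the transcription factor Klf2 (-1.15) and Cpne8 (-1.12). Both probes for the transferrin receptor Tfrc fell, at -1.22 and -1.15. Scara5, a ferritin receptor, fell by 1.28, with -1.88 and -0.68 on the arrays. Rpp14, a subunit of ribonuclease P, was not above background in the Dlx3 channel on either array and was at least 1.80-fold lower (adjusted p = 0.0158, and 0.0685 without the second stable array). By size alone, 31 probes were over 2-fold higher and 14 over 2-fold lower on both stable arrays. The call of Mmp2 ended in the fit on the stable arrays alone (adjusted p = 0.0514) and with plain background subtraction, and robust eBayes ended the calls of Mmp2 and Il33.

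Among the fixed gene lists, the interferon response had 11 of 32 measured genes higher, 3 lower and 18 not passing in stable transfectants (13 higher and 3 lower adjusted over the list alone). Its leading members were Ifit2 (1.08), the chemokine Ccl5 (0.71), the GTPase Irgm1 (0.69) and Isg15 (0.68, at 1.02 and 0.34 on the arrays). This was the only list called by camera in this contrast (mean 0.24, adjusted p = 0.0145). Bone and cartilage (mean 0.34), cholesterol synthesis (0.29) and inflammatory cytokines (0.27) had larger means but were not called. The interferon call was lost in the version with an estimated correlation (adjusted p = 0.809) and without the first stable array (mean 0.15). Inflammatory cytokines had 6 higher, 1 lower and 14 not passing (9 and 2 adjusted over the list alone), led by Cxcl5, Cxcl1 (1.05, at 0.55 and 1.54), Ccl2 (0.85, at 0.31 and 1.40) and Relb (0.66). Immediate early genes had 9 higher, 3 lower and 11 not passing (10 and 3 over the list alone), among them Nr4a1 (1.33), Fos (0.97), Btg2 (0.91) and, downward, Klf2. Of 11 cholesterol synthesis genes 5 rose and 6 did not pass (6 higher over the list alone), led by Dhcr7 (0.66), Cyp51 (0.65, at 0.30 and 1.00), Msmo1 (0.54) and Sqle (0.42, at 0.19 and 0.65). In this contrast 22.7% of all tested probes were called, so a count near that share does not set a list apart.

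In stable transfectants, extracellular matrix and TGF-beta targets had 11 higher, 5 lower and 20 not passing (14 and 7 adjusted over the list alone), with Mmp2, Mmp14 (1.28), Tgfbr2 (1.17, at 0.66 and 1.68) and Fbln1 (1.03, at 0.65 and 1.41) at the top. Bone and cartilage genes had 5 higher, 0 lower and 13 not passing (5 and 0 over the list alone). Spp1, the proteoglycan decorin Dcn (1.00), alkaline phosphatase Alpl (0.77) and Comp (0.61) changed most among them. Neither list was called by camera (adjusted p = 0.325 for matrix and 0.0628 for bone). BMP signalling and antagonists had 4 higher and 3 lower of 25 (5 and 3 over the list alone). The inhibitors of differentiation Id3 (-0.84, at -1.22 and -0.46) and Id2 (-0.75) fell, whereas Fstl1 (0.56) and Bmp8a (0.53, at 0.31 and 0.74) rose. The WNT pathway had 5 higher and 4 lower of 28 (6 and 4 over the list alone), with Wnt10b down and the receptor Fzd1 (1.05), the feedback gene Axin2 (0.70) and Tcf7 (0.59) up. p53 targets and growth arrest genes had 8 higher and 3 lower of 17 (8 and 4 over the list alone), with Gas1, Btg2 and Pmaip1 (0.73) up and Gadd45g down (-0.92). LIF and IL6-family signalling had 5 higher and 3 lower of 15 (6 and 3 over the list alone), with Clcf1 (-0.69) and Jak2 (-0.50) down and Lifr and Osmr (0.45) up.

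In stable transfectants, muscle genes had 3 higher and 3 lower of 25 (3 and 3 adjusted over the list alone), with Acta2, Tagln and Cnn1 (-0.42), which belong to smooth muscle and contractile fibroblasts, lower and Myf5 (0.44) higher. Over all tested probes, 22.7% were called. Epidermal genes had 2 higher and 4 lower of 25 (2 and 5 over the list alone), led by Dsc3 (-0.82), Dsc1 (0.68), Krt19 (-0.57) and Krt17 (-0.52). Trophoblast and placental genes had 4 higher and 1 lower of 15 (5 and 4 over the list alone), among them Cdkn1c, Rhox6 (0.59, at 0.34 and 0.84), Pgf (0.52) and Ascl2 (-0.37). Pluripotency genes had 1 higher and 3 lower of 14 (1 and 3 over the list alone), with Nanog up (0.72) and Klf2, Pou5f1 (-0.53, at -0.34 and -0.72) and Tdgf1 (-0.39, at -0.21 and -0.58) down. Adipocyte genes had 2 higher and 1 lower of 11 (3 and 1 over the list alone), namely Cebpd (0.89), Scd2 (0.30) and Pparg (-0.44, at -0.23 and -0.66). In the macrophage and blood list Hbb-y (0.83) and Spi1 (0.38, at 0.54 and 0.21) rose among 11 (2 higher over the list alone), and in the endothelial list Sox18 (0.40) rose among 11 (0 over the list alone). The neural list had 1 call among 12, Tubb3 (-0.89, at -0.58 and -1.20), and 1 over the list alone. Members of these lists were not checked one by one against the randomized oligonucleotides. Of those, 54.2 and 52.6% lay above local background on the stable arrays, so signal without a target was not excluded for these members.

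Cell cycle genes in stable transfectants had 3 higher and 6 lower of 35 (4 and 9 adjusted over the list alone), with Rrm2 (-0.66) and Cdc25c (-0.55) down and Mcm4 (0.48) and Mcm7 (0.46) up. The share called over all tested probes was 22.7%. Oxidative phosphorylation had 1 higher and 8 lower of 43 (0 and 4 over the list alone), led by Atp5c1 (-0.60), Cox5a (-0.52, at -0.35 and -0.70), Cycs (-0.51, at -0.79 and -0.23) and Uqcrfs1 (-0.48). Ribosomal proteins had 2 higher and 5 lower of 59 (1 and 1 over the list alone), led by Rpl7 (-0.63), Rpl13a (0.53), Rpl21 (0.47) and Rpl27 (-0.43). The heat shock and unfolded protein list had 2 higher of 21 (2 over the list alone), Ddit3 (0.49) and Pdia6 (0.35). HOX genes had 2 higher and 1 lower of 17 (0 and 1 over the list alone), namely Hoxd10 (0.35, at 0.50 and 0.19), Hoxc4 (0.27) and Hoxb5 (-0.38). None of 7 DLX and MSX genes was called by limma, adjusted over all genes or over the list alone, with Msx2 at -0.35 (adjusted p = 0.0594) and Dlx4 at 0.30 (adjusted p = 0.0938). The endothelial list had a median of -0.03, a mean of 0.03 and a downward camera direction.

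**Figure D2:**
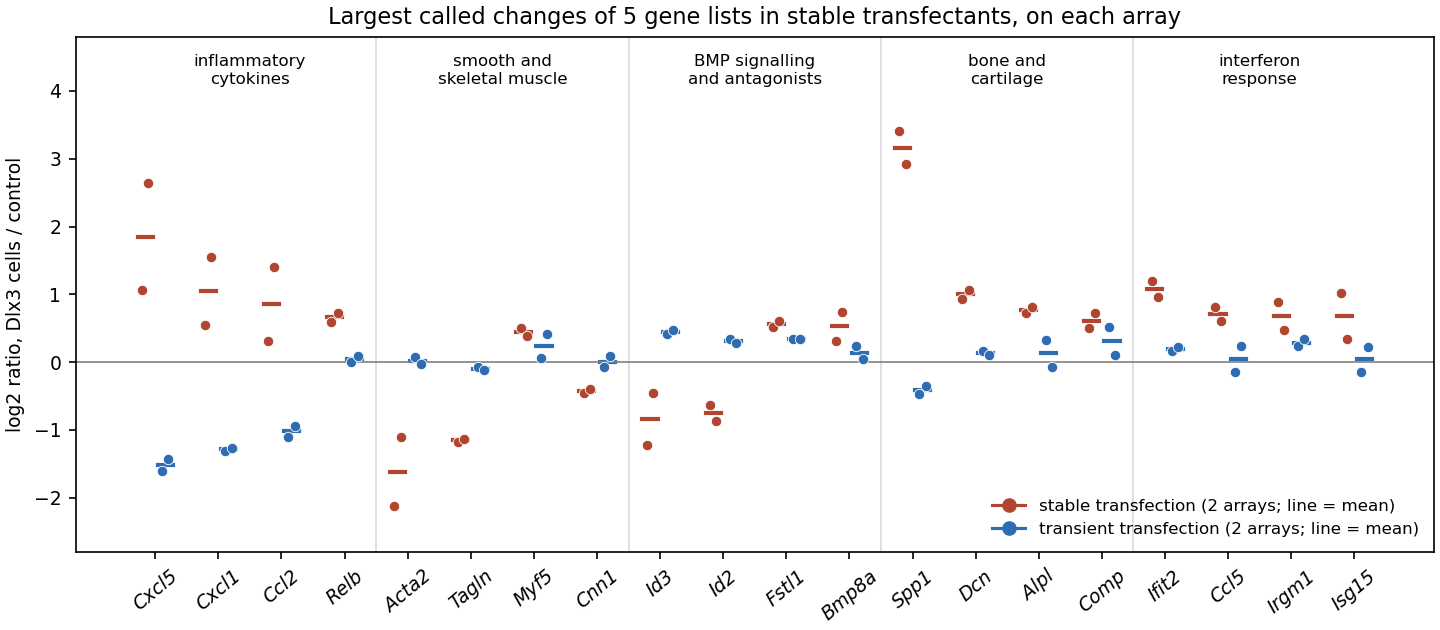
Log2 ratio of Dlx3 cells over control for the 4 called genes with the largest stable change in each of 5 gene lists, with a point for each array and a line at each mean of 2 arrays. Cxcl5, Cxcl1 and Ccl2 lie above 0 on both stable arrays and below 0 on both transient arrays, whereas Id2 and Id3 lie below 0 on the stable and above 0 on the transient arrays.

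After 24 h of transient transfection, 21 of 14613 probes differed from control MEFs, 14 higher and 7 lower, and 2958 had an unadjusted p under 0.05 in limma. The ATP-gated channel P2rx1 rose at least 6.47-fold (n = 2, adjusted p = 0.00171), a nominal lower bound since its control channel was not above background on either array. The small proteoglycan Ogn rose by 1.46 ± 0.16 (SD, n = 2), Cthrc1 by 1.20 ± 0.11 and the kinase Camk4 by 1.06 ± 0.15 (adjusted p = 0.0418, 0.0227 and 0.0407). Serf1 read 1.98-fold higher, but its control channel was not above background on either array. This value is therefore a ratio to an undetected signal, and neither a measured size nor a lower bound. The matrix protein Tgfbi rose by 0.97, the lipid carrier Apod by 0.93 and the stress-response gene Sesn3 by 0.79.

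Among the genes that fell in transient transfectants, Gfra2, a receptor for neurotrophic factors, fell by 1.15 ± 0.05, Nfkbiz, a regulator of NF-kB, by 1.06 ± 0.12 and the collagen gene Col8a1 by 0.90 ± 0.01 (adjusted p = 0.0248, 0.0459 and 0.0248). The WNT transcription factor Lef1 (-0.87), the tetraspanin Cd151 (-0.81) and the HSP90 co-chaperone Fkbp4 (-0.69) fell as well. By size, 11 probes were over 2-fold higher and 4 over 2-fold lower on both transient arrays. After scaling between arrays, 31 probes were past 2-fold on both transient and 22 on both stable arrays, against 15 and 45 here. The number of calls rested on the spread that the groups share, since the fit on the transient arrays alone called 1288 probes, while leaving out the first transient array left 3 and leaving out the second left 11. Of the named genes, P2rx1 passed without either transient array, and the other 13 given here passed in neither case (adjusted p = 0.0977 to 0.435). Plain background subtraction called 0 probes with limma, and print-tip loess ended the calls of Lef1, Cd151, Fkbp4, Nfkbiz and Sesn3. Median centring in place of loess gave 143 higher and 504 lower, scaling between arrays gave 623 and 777, and print-tip loess gave 12 and 3, against 14 and 7 here.

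Gene list means lay small amounts away from 0 in transient transfectants, where ratios of transcript spots spread no wider than those of spots without a target. At the preset correlation camera called 10 of 24 lists. Each had an adjusted p of 0.591 in the version with an estimated correlation, which has 2 residual degrees of freedom. Inflammatory cytokines were lower as a list (mean -0.36, camera adjusted p = 0.000733). No member of the 21 measured was called over all genes, but 8 were lower adjusted over the list alone, with Saa3 at -0.46 and Cxcl1 at -1.29 (both adjusted p = 0.0663). Oxidative phosphorylation (mean -0.21) and ribosomal proteins (mean -0.20) were also lower, with 9 of 43 and 3 of 59 members lower adjusted over the list alone and 0 over all genes. Their leading members were Cycs (-0.72), Cox6c (-0.55), Rpl27 (-0.59) and Rpl35 (-0.42), none of which passed (adjusted p = 0.0847, 0.0851, 0.0828 and 0.0847).

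The other 7 called lists were higher in transient transfectants. Bone and cartilage genes had a mean of 0.18 (adjusted p = 0.00491), with Sox9 at 0.52 and Col1a2 at 0.33 (adjusted p = 0.0663 and 0.149). The interferon response had a mean of 0.15 (adjusted p = 0.00257), with Irf7 at 0.47 and B2m at 0.52 (adjusted p = 0.0779 and 0.113). BMP signalling and antagonists had a mean of 0.18 (adjusted p = 0.0147), with Bmp4 at 0.66 and Fstl1 at 0.34 (adjusted p = 0.0615 and 0.0988). Extracellular matrix and TGF-beta targets (mean 0.13, adjusted p = 0.0197) had 0 higher and 2 lower over all genes. Col8a1 fell against the direction of the list, whose mean was -0.003 with median centring. Cholesterol synthesis (mean 0.16, adjusted p = 0.0236, with Dhcr7 at 0.35 and Lss at 0.54), p53 targets and growth arrest (mean 0.17, adjusted p = 0.0406, with Cdkn1b at 0.50 and Gadd45a at 0.96) and LIF and IL6-family signalling (mean 0.13, adjusted p = 0.0412, with Lifr at 0.79 and Il6st at 0.32) had no called member. The title genes Lifr and Chrdl1 belong to the LIF and BMP lists, which were not tested without them. Adjusted over the list alone, the counts higher and lower were 1 and 0 for bone and cartilage, 1 and 0 for interferon, 2 and 0 for BMP, 3 and 3 for matrix, 0 and 0 for cholesterol, 4 and 1 for p53 and 2 and 0 for LIF.

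Of these 7 calls in transient transfectants, 6 ended when a transient array was left out. Without the first transient array the bone and cartilage (adjusted p = 0.071), matrix (adjusted p = 0.0786), p53 (adjusted p = 0.0822) and LIF (adjusted p = 0.166) lists were not called. Without the second, the interferon response (mean 0.05, adjusted p = 0.443) and cholesterol synthesis (adjusted p = 0.122) were not called. Median centring ended the calls of the interferon, BMP, matrix, cholesterol, p53 and LIF lists, and the authors' values ended these and that of bone and cartilage.

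Of the 14 lists that camera did not call in transient transfectants, only the WNT pathway held a called gene, Lef1, with 8 higher and 2 lower of 28 adjusted over the list alone. Immediate early genes had 2 higher and 2 lower of 23 over the list alone, with Fos at 0.78 and Klf2 at 0.49 (both adjusted p = 0.0663). The adipocyte list had 1 higher and 1 lower, the pluripotency and heat shock lists 1 higher each, and the epidermal list 1 lower over the list alone. The DLX and MSX, HOX, trophoblast, cell cycle, muscle, endothelial, macrophage and blood, and neural lists had 0 by limma over the list alone. Medians and means differed in sign for immediate early genes (-0.05 and 0.004), pluripotency (-0.03 and 0.009), epidermis (0.05 and -0.008) and trophoblast (-0.002 and 0.04).

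**Figure D3:**
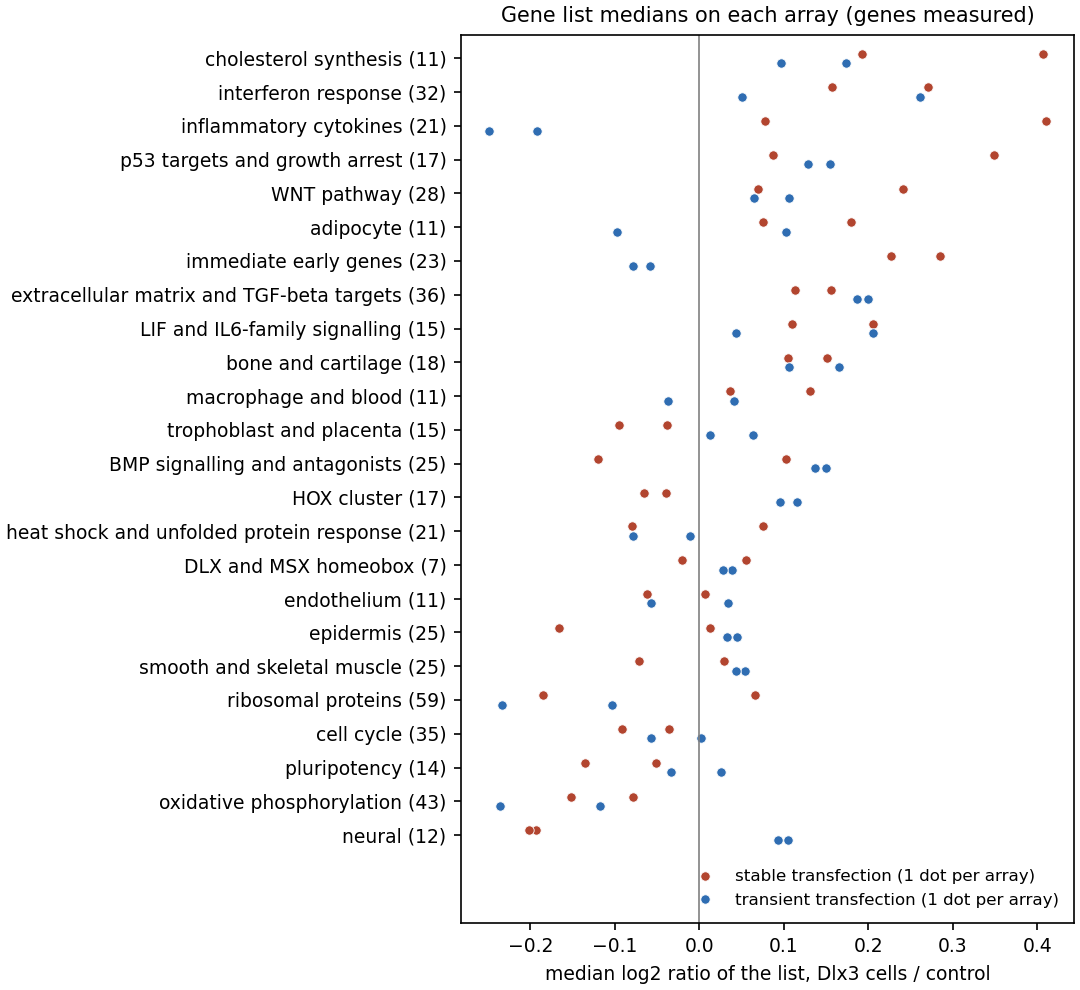
Median log2 ratio of Dlx3 cells over control for each gene list on each array, with the number of genes measured in parentheses and separate colours for stable and transient transfection. Inflammatory cytokines lie at 0.08 and 0.41 on the stable arrays and at -0.25 and -0.19 on the transient arrays, and the neural list at -0.19 and -0.20 against 0.09 and 0.11.

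The ratio over control differed between stable and transient transfection at 35 of 14611 probes, 20 higher and 15 lower in the stable group. An unadjusted p under 0.05 in limma was reached by 2853 probes. The control was empty-plasmid cells in the stable and control MEFs in the transient group, so the kind of control can underlie these differences. Plain background subtraction called 0 probes for this difference with limma. Among the called named genes Spp1 differed most, at 3.17 in stable and -0.41 in transient transfectants, a difference of 3.58 ± 0.18 (SE, adjusted p = 0.0102), followed by Msln (3.02 ± 0.24, adjusted p = 0.0218), Tcim (2.76 ± 0.23) and Enpp2 (1.88 ± 0.12). Nfkbiz differed by 1.78, the transcription factors Bhlhe40 and Cebpd by 1.42 and 1.34, and the growth factors Pdgfc and Fgf7 by 1.20 each. Col8a1 (1.34) and Tmem86a (1.22) were higher too. Errfi1, an inhibitor of the EGF receptor, was called higher, but its Dlx3 channel was not above background on either transient array, so no size is given.

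Lower in the stable than in the transient group were Ndrg4 (-2.26 ± 0.14, adjusted p = 0.0194), Ogn (-1.83 ± 0.20), Klf2 (-1.65 ± 0.12), Khdrbs3 (-1.62 ± 0.17), Id2 (-1.06), Tagln (-1.06) and Lrrc71 (-0.93). P2rx1 and the oestrogen sulfotransferase Sult1e1 were called lower, but neither channel was above background for P2rx1 on the stable arrays or for Sult1e1 on the transient arrays, so no size is given. Klf2 read -1.15 in stable and 0.49 in transient transfectants, and Id2 read -0.75 and 0.31. A probe described as inhibitor of DNA binding 1, picked after its values were seen, went the same way (-1.23 and 0.31, difference adjusted p = 0.0302). Cxcl1 (2.34) and Cxcl5 (3.37) did not pass (adjusted p = 0.0577 and 0.0673), nor did Cdkn1c (1.93, adjusted p = 0.0777). Without the first transient array 3 probes were called and without the second 7, whereas without the first stable array 1345 were called and without the second 258. Of the named genes Spp1 and Ndrg4 passed without either transient array.

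**Figure D4:**
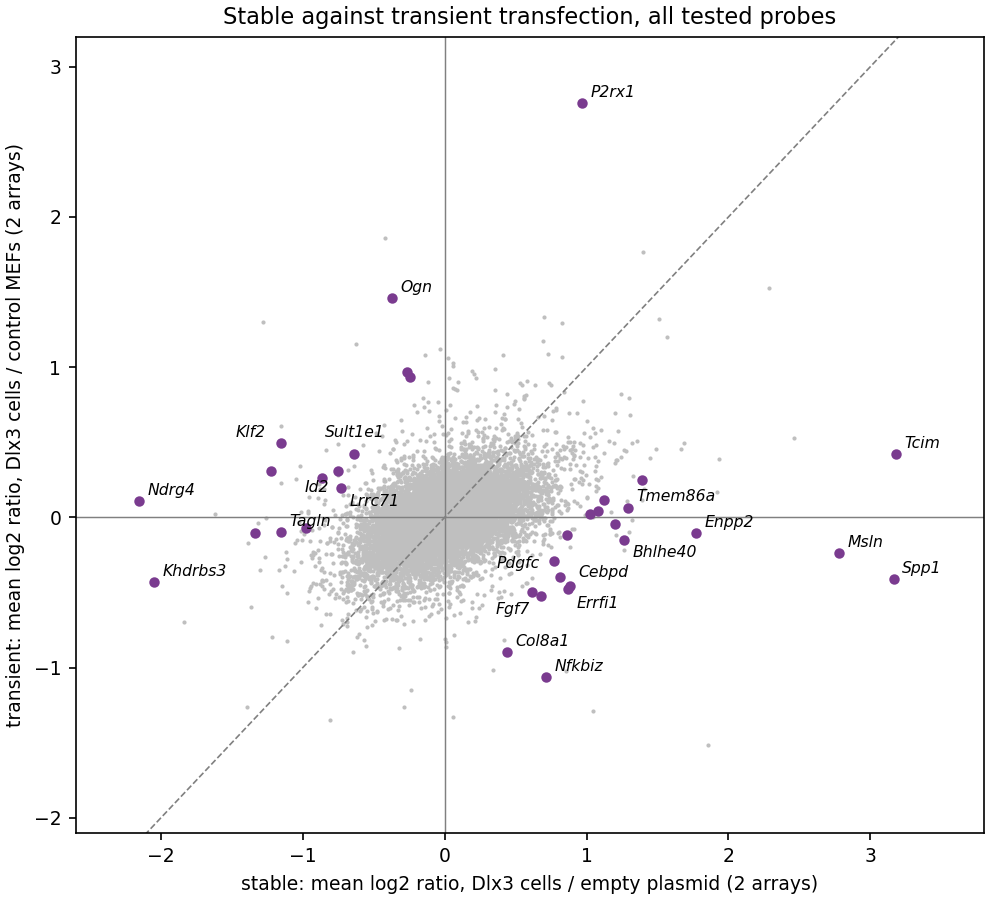
Mean log2 ratio in stable transfectants (horizontal, 2 arrays) against that in transient transfectants (vertical, 2 arrays) for all tested probes, with the 35 probes called in stable minus transient enlarged and a dashed line of equal values. Spp1, Msln and Tcim lie far to the right at 3.17, 2.78 and 3.18, and P2rx1 lies at 2.76 on the vertical axis, with its control channel not above background on the transient arrays.

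Of the lists, 4 differed between the groups by camera, and for each the adjusted p was 0.874 with an estimated correlation. Inflammatory cytokines were higher in the stable group by a mean of 0.63 (adjusted p = 0.000233), with 17 of 21 members positive and 9 higher adjusted over the list alone, although none passed over all genes. The neural list was lower by a mean of -0.30 (adjusted p = 0.00372), with 11 of 12 members negative and 0 calls by limma over all genes or the list alone, led by Pax6 (-0.59) and Map2 (-0.43), both not passing (adjusted p = 0.179 and 0.188). Immediate early genes were higher by a mean of 0.22 (adjusted p = 0.037), with 5 higher and 1 lower of 23 over the list alone, yet the call over all genes, Klf2, was in the opposite direction. Ribosomal proteins were higher by a mean of 0.16 (adjusted p = 0.0314), with 0 of 59 members called by limma over all genes or the list alone. Without the first stable array the mean difference was 0.03 for ribosomal proteins (adjusted p = 0.963) and 0.18 for immediate early genes (adjusted p = 0.311), and without the first transient array it was 0.08 (adjusted p = 0.445) and 0.19 (adjusted p = 0.11), respectively. In lists that camera did not call, Cebpd, Id2, Spp1, Col8a1, Tagln and Klf2 passed over all genes in the adipocyte, BMP, bone, matrix, muscle and pluripotency lists, and Axin2 (0.85, adjusted p = 0.0577) and Ifit2 (0.89, adjusted p = 0.0673) did not. Medians and means differed in sign for bone and cartilage (-0.02 and 0.16), trophoblast (-0.03 and 0.13), adipocyte (-0.02 and 0.12), LIF signalling (0.04 and -0.04) and endothelium (-0.03 and 0.008).

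Across all 4 arrays, 3259 probes had a mean log2 ratio different from 0, 1615 higher and 1644 lower. Tcim rose by 1.80 ± 0.12 (SE), Cdkn1c by 1.49 ± 0.14 and Cthrc1 by 1.39 ± 0.06 (adjusted p = 0.00513, 0.00532 and 0.00144). These SEs hold the spread within the groups and leave out the gap between them. The stable and transient means were 3.18 and 0.42 for Tcim, 2.46 and 0.53 for Cdkn1c, and 1.57 and 1.20 for Cthrc1. P2rx1 and the antisense transcript gene Alkbh3os1 were called higher, but P2rx1 had neither channel above background on the stable arrays, and neither gene had its control channel above background on the transient arrays, so no size is given. The further rises were of Fuca2 (1.06), the antioxidant enzyme Gpx1 (1.02), Enpp1 (0.99), Rin2 (0.97), Klhl24 (0.95), the ectodysplasin receptor Edar (0.93) and Gas1 (0.92). Khdrbs3 fell by 1.24 ± 0.09 (-2.05 in stable and -0.43 in transient transfectants), the Tfrc probes by 1.00 and 0.80, Wnt10b by 0.98 ± 0.08 and the small GTPase Rras2 by 0.97. Tmeff2 (-0.83), the AP-1 subunit Fosl1 (-0.79), Igfbp7 (-0.77), Gps1 (-0.76) and Srp9 (-0.74) fell as well. The value of Gpx1 leaned on the first transient array, at 2.30, and was 0.53 without it (adjusted p = 0.0527). Without either transient array, Igfbp7 (adjusted p = 0.0878 and 0.0807) and Tmeff2 (adjusted p = 0.0676 without the first) did not pass, nor did Alkbh3os1 without the second stable or second transient array (adjusted p = 0.0504 and 0.0625), nor did Enpp1 and Fosl1 without the first (both adjusted p = 0.051). Without the first transient array 221 probes were called, and without the second 250.

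Camera called 5 lists over the 4 arrays, each with an adjusted p of 0.742 with an estimated correlation, or 0.828 for ribosomal proteins. The share of all tested probes called in this contrast was 22.3%. The interferon response (mean 0.20, adjusted p = 0.000931) had 13 higher and 2 lower of 32 and 16 and 3 adjusted over the list alone, led by Ifit2 (0.64), B2m (0.52), Ifi44 (0.50) and Irf9 (0.50). Bone and cartilage (mean 0.26, adjusted p = 0.00166) had 6 higher of 18 and 7 over the list alone, led by Spp1 (1.38, with 3.17 in stable and -0.41 in transient transfectants), Dcn (0.57), Comp (0.46) and Alpl (0.45). Cholesterol synthesis (mean 0.23, adjusted p = 0.015) had 4 higher of 11 and 8 over the list alone, namely Lss (0.53), Dhcr7 (0.51), Msmo1 (0.34) and Fdft1 (0.29). Oxidative phosphorylation (mean -0.16, adjusted p = 0.00045) had 14 lower of 43 and 16 over the list alone, led by Cycs (-0.61), Atp5c1 (-0.52), Cox5a (-0.39) and Cox8a (-0.36). Ribosomal proteins (mean -0.12, adjusted p = 0.0102) had 2 higher and 10 lower of 59 and 2 and 9 over the list alone, led by Rps23 (-0.55) and Rpl27 (-0.51). Without the second stable array ribosomal proteins (mean -0.05, adjusted p = 0.315) and cholesterol synthesis (adjusted p = 0.0638) were not called, nor were ribosomal proteins without the first transient array (mean -0.08, adjusted p = 0.105). Among the remaining lists, LIF signalling had 5 higher and 2 lower of 15 with Lifr on top, BMP signalling 5 higher and 1 lower of 25 with Chrdl1 (0.93) and Bmp4 (0.54) on top, and the WNT pathway 9 higher and 4 lower of 28 with Wnt10b (-0.98), Fzd1 (0.82) and Lef1 (-0.60) leading.

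Stable and transient group means correlated across 14611 probes with Pearson r = 0.431 and Spearman rho = 0.436, and array pairs between the groups with r = 0.332 to 0.376. Of probes called in stable transfectants, 2706 of 3320 (81.5%) had the same sign in the transient means, and 16 of 21 (76.2%) called in transient transfectants had the same sign in the stable means. Both groups called 7 probes higher, against 1.62 for independent lists, namely Cthrc1, P2rx1, Serf1, Sesn3, a RIKEN clone and probes described as growth arrest specific 2 and matrix Gla protein. P2rx1 had neither channel above background on the stable arrays. Both called 2 probes lower, Lef1 among them, against 0.779 for independent lists. By size, Cthrc1, growth arrest specific 2 (1.51 and 1.32) and matrix Gla protein (2.29 and 1.53) were over 2-fold higher on all 4 arrays, 3 probes against 0.0233 for independent lists, and no probe was over 2-fold lower on all 4. Genes of these counts outside the naming rule were named after their values were seen. Since the dyes were not exchanged on any array, part of the agreement can come from probe-specific dye effects. Both contrasts also use the same estimate of spread per probe, so the called lists are not independent even where the ratios are.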

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

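The tests of the dye effect on the differences between the groups, of probes with opposite signs, of the Dlx3 spot against randomized oligonucleotides and of neighbouring spots were chosen only after the results were seen.

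Stable and transient transfectants differed in their ratio over control at 35 probes, by a limma test of the difference itself, which called 0 probes with plain background subtraction. Among the named genes, those higher in the stable group were Spp1 (3.58), Msln (3.02), Tcim (2.76), Enpp2 (1.88), Nfkbiz (1.78), Bhlhe40 (1.42), Cebpd (1.34), Col8a1 (1.34), Tmem86a (1.22), Pdgfc (1.20) and Fgf7 (1.20). Those lower were Ndrg4 (-2.26), Ogn (-1.83), Klf2 (-1.65), Khdrbs3 (-1.62), Id2 (-1.06), Tagln (-1.06) and Lrrc71 (-0.93). Errfi1 was called higher, and P2rx1 and Sult1e1 lower (adjusted p = 0.0226, 0.0218 and 0.0302), but each had a channel that was not above background on either array of a group, so no size is given. By camera, inflammatory cytokines (0.63), the neural list (-0.30), immediate early genes (0.22) and ribosomal proteins (0.16) differed as well, each with an adjusted p of 0.874 with an estimated correlation.

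Of the 35 probes, 22 had one sign on both stable arrays and the opposite sign on both transient arrays. Some lay away from 0 in both groups, such as Nfkbiz (0.72 in stable and -1.06 in transient), Col8a1 (0.44 and -0.90) and Klf2 (-1.15 and 0.49). For such probes this argues against wider ratios on the stable arrays, and against a probe-specific dye effect that keeps its sign over arrays. It decides little where transient values lay near 0, as for Enpp2 (-0.21 and -0.01), since blank spots had a transient SD of 0.26. The 35 probes were also picked for a large difference, which favours opposite signs. For the other 13 probes a dye effect of unequal size stays open, and so do wider ratios, since 68.6% of the 35 passed after scaling between arrays. The stable group was set against empty-plasmid cells and the transient group against control MEFs, and 0 arrays set Dlx3 cells against the other kind of control. The kind of control, the length of transfection and the plasmid itself therefore cannot be told apart, and no biological explanation was tested.

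The correlation of r = 0.431 between the group means over probes was weighed next. Errors at dim spots are argued against as its whole source, since r was 0.477 (95% interval 0.44 to 0.514) over the 4871 brightest probes and 0.359 over the 4870 dimmest. Position on the slide may contribute, because r was 0.367 (95% interval 0.305 to 0.43) over 1006 control spots, 0.371 over 814 blanks and 0.035 over 192 randomized oligonucleotides. Setting each spot against the next spot in the row gave r = 0.182, against 0.434 for the spot itself over 12543 spots. With 0 arrays that exchange the dyes, a probe-specific dye effect and a shared response to Dlx3 cannot be told apart.

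The Dlx3 probe was not called in either group although Dlx3 was the transfected gene. Saturation is argued against, with at most 0% of pixels saturated at the Dlx3 spot. A spot at the level of no target stays open, since the Dlx3 channel exceeded the 95th percentile of the randomized oligonucleotides on 0 of 4 arrays, although it lay above 91.7 to 92.7% of them. A probe outside the transfected sequence stays open, because 0 probe sequences were read. No biological explanation was tested.

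Randomized oligonucleotides, which the comparisons do not use, gave signal above local background at 28.6% of spots on the lowest array and 54.2% on the highest. Local background thus understates the signal of a probe with no target, and a stricter filter was added for this reason after the data were seen.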

How the results depend on the processing

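The filter against randomized oligonucleotides was chosen only after the data were seen, and all other alternatives were fixed earlier. Aquantile normalization leaves log ratios unchanged by construction. No batch alternative was run, and fits on a group alone were not run for the difference or the 4-array mean, which need both groups. For the changes of count below the cause was not tested, except where fewer arrays or probes were fitted.

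Named genes kept their direction and their side of the threshold in 390 of 394 cases in the stable group, 209 of 244 in the transient group, 326 of 364 for the difference and 403 of 412 for the 4-array mean, over all alternatives but leaving out arrays, counting only alternatives that tested the gene. The filter against randomized oligonucleotides did not test 11 of 24 named probes in the stable group, 7 of 15 in the transient group, 15 of 21 for the difference and 12 of 24 for the mean. When arrays were left out these were 93 of 96, 33 of 60, 56 of 96 and 95 of 108. Leaving out either stable array gave the same transient fit, that of the transient arrays alone. Leaving out either transient array likewise gave the fit of the stable arrays alone. Both fits are also counted among the 394 and 244 cases above. Such repeats do not test whether a call rests on a single array of its own group. The 93 of 96 and 33 of 60 therefore overstate stability. The lists called by camera kept their direction and their side of the threshold in 16 of 19, 144 of 190, 61 of 75 and 83 of 95 cases, respectively. In the stable group Il33 lost its call with robust eBayes.

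With no background correction, 42 probes were called in the transient group, and the group means correlated with r = 0.463. A normexp offset of 10 gave 22 probes for the difference and 25 past 2-fold on both transient arrays. Plain background subtraction called 2072 probes in the stable group, 0 in the transient group and 0 for the difference by limma, with 83 and 39 past 2-fold on both stable and both transient arrays, r = 0.407 and 2 lists for the difference. With median pixel intensities 52 probes were called in the transient group, 28 of them higher and 24 lower, 54 for the difference and 4 lists in the stable group.

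Print-tip loess called 1903 probes for the 4-array mean and 3 lists in the stable group, with r = 0.341. Median centring called 647 probes in the transient group and 88 for the difference, with r = 0.452, 4 lists in the stable and 6 in the transient group. Under it the transient Lifr value of 0.76 passed (adjusted p = 0.0226), and the matrix list in the transient group changed sign to -0.003. Scaling between arrays called 2141 probes in the stable and 1400 in the transient group, with 22 and 31 past 2-fold on both arrays. Under scaling the transient values of Lifr (0.95, adjusted p = 0.00712) and Chrdl1 (1.41, adjusted p = 0.02) passed. The authors' values called 223 probes in the transient group, with transient Lifr at 0.89 (adjusted p = 0.0474), 73 and 31 past 2-fold on both arrays, and 4 lists in the stable and 3 in the transient group. The median of all probes stayed within 0.01 of 0 under each of these. For print-tip loess, median centring and scaling, this is set by the normalization and is no check on the results.

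With no filter on dim probes 12 probes were called in the transient group and 2 lists in the stable group. Requiring signal on all 4 arrays gave 100 probes, transient Lifr at 0.79 (adjusted p = 0.0446) and 0 lists in the stable group by camera. Leaving out all negative marks gave 52 probes in the transient group and 2 lists in the stable group. The filter against randomized oligonucleotides, which tests 4482 probes and none of Dlx3, Lifr and Chrdl1, called 1324 in the stable group, 103 in the transient group, 12 for the difference and 1465 for the 4-array mean. It also gave 21 past 2-fold on both stable arrays, r = 0.472, and 3 lists in the stable and 4 in the transient group. Of the 21 transient calls, 11 were called under it.

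Fitted alone, the stable group called 1228 probes and the transient group 1288, with transient Lifr at 0.79 (adjusted p = 0.0182) and Chrdl1 at 1.17 (adjusted p = 0.00805). At 1.5-fold on both arrays 347 probes passed in the stable and 102 in the transient group. With an estimated correlation 0 lists were called in the stable group, 0 in the transient group, 0 for the difference and 0 for the mean. That version has 2 residual degrees of freedom, so these counts do not show an effect of the correlation. The directional test of fry called 0, 0, 0 and 0. The mixed test of fry, which takes changes in either direction, called 22, 12, 12 and 22 of 24 lists. Camera at the preset correlation called 1, 10, 4 and 5.

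Leaving out an array gave 1228 to 4350 probes in the stable group, 3 to 1288 in the transient group, 3 to 1345 for the difference and 221 to 4968 for the mean. The lowest counts came without a transient array and the highest without the first stable array, the transient count being equal without either stable array. The correlation of group means was 0.373 to 0.408. Lifr ranged from 0.38 to 0.74 in the stable and from 0.74 to 0.84 in the transient group, and Chrdl1 from -0.06 (without the second stable array) to 1.45 and from 1.14 to 1.20. The difference for Dlx3 ranged from -0.417 to 0.002, changing sign without the second transient array. That for Chrdl1 ranged from -1.23 (adjusted p = 0.0149) without the second stable array to 0.28 without the first. Lists called were 2 to 4 in the stable group, 6 to 11 in the transient group, 2 to 6 for the difference and 3 to 7 for the mean.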
